A study of Homo sapiens with 6 samples.

How the data were processed

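RNA from 6 cultures of MDA-MB-231 cells was measured on 1-colour Affymetrix Human Gene arrays, 3 for cells with GHSROS in the pTargeT vector and 3 for cells with the empty vector. The groups and replicate numbers were taken from the sample titles. The deposited values are log2 expression per probe set, made by the authors with RMA per the submitters' processing notes, and the version of RMA, its background, normalization and summary steps and any filter on probe sets are not given in the sources used here. RMA as usually run corrects background and quantile normalizes the arrays, and the normalization removes a shift of most genes together. Differences of dim probe sets can stay compressed in such values. The arrays' medians differed by at most 0.09, no value was missing, and 0 columns of array values were left out. Array values carry no read depth, and the number of arrays limits the precision.

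Of 28869 probe sets, 19310 were paired with 1 gene symbol by the platform annotation, 1752 with several symbols and 7807 were not listed there and stayed unnamed. Entrez identifiers of 19279 probe sets were found in a RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols and was used for names, chromosomes and the order of neighbouring genes, with no coordinates printed. Probe sets with several symbols were not named. For each gene the probe set with the highest mean over the 6 arrays was kept, which left 18377 genes with no filter on level and no further normalization. The strand read by the probe sets is not given in the sources used here.

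GHSROS was compared with the empty vector in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05 on the adjusted p, and a second count asked for a fold change of at least 1.5. Log2 fold changes are GHSROS minus empty vector, with moderated standard errors. Tests treat the cultures as independent, as the submitters' term biological replicate implies. If they were not grown and transfected separately, the p-values measure only the spread between these samples.

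27 gene lists were fixed before the data were examined, as were the tests and the first set of alternatives. They covered MHC class I and class II antigen presentation, interferon-stimulated genes, NF-kB and inflammation, mesenchymal and epithelial genes, matrix proteases and migration, lung and bone metastasis genes of this line, cell cycle phases, p53, ATF4, hypoxia, immediate early, TGF-beta and NRF2 targets, lipid synthesis, ribosomal proteins, oxidative phosphorylation, histones, the ghrelin axis and markers of 5 kinds of other cells. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 27 lists, with camera at an estimated correlation and fry as alternatives. Each chromosome's genes were tested in the same way.

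The rule for named genes, set in advance, took GHSR and GHRL, the 10 genes with the smallest p in each direction if none passed, and the 2 members with the largest absolute difference in each list without a member past the test, leaving out sex-linked expression markers. The alternatives fixed in advance were the replicate number as a block, quantile normalization, median centring, filters at the median and at the 25th percentile of level, all probe sets, the mean of a gene's probe sets, an intensity trend with a robust prior, array weights and leaving out each array. Alternatives added after the data were seen were the mean of the mitosis list or of the ATF4 list as a covariate, both arrays numbered 3 left out, empty-vector array 1 with GHSROS array 3 left out, and the omissions of arrays repeated with an estimated correlation.

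The test was tried on simulated data for the comparison of GHSROS with the empty vector over 18377 genes. With 200 genes shifted in the deposited values, limma recovered 75% at a 2-fold shift, 96.5% at 4-fold and 100% at 8-fold, and called 3, 5 and 5 other genes. Shifting 200 genes at once makes the adjustment more lenient, so these shares do not hold where only a few genes change. In the real comparison ZNF585B, 2.31-fold lower at an unadjusted p of 5.9e-05 in limma, did not pass. With independent noise of the same spread it recovered 73%, 94% and 98.5%, and called 12, 10 and 7 other genes.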

Results

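The series measured RNA levels in MDA-MB-231, an established human breast cancer cell line of mesenchymal, triple-negative character, after transfection with the pTargeT mammalian expression vector carrying GHSROS or with the same vector left empty. GHSROS is a long noncoding RNA transcribed from within GHSR, the ghrelin receptor gene, on the opposite strand. Total RNA from 3 cultures per group, described by the submitters as biological replicates, was hybridised to 6 Affymetrix Human Gene arrays. The deposited log2 values covered 28869 probe sets on every array, with array medians between 6.559 and 6.648. The comparison of both vectors asks which genes differ in level when the cells are made to express GHSROS, and the precision of every value below is limited by 3 arrays per group.

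The 5 genes with the smallest p, ZNF585B, NLRP2, LOC645188, NDP and PTPN22, were lower in the GHSROS arrays. ZNF585B, a zinc finger gene read by probe set 8036389, averaged 7.58 ± 0.23 (SD, n = 3) with the empty vector and 6.37 ± 0.15 (SD, n = 3) with GHSROS, a log2 fold change of -1.21 (SE 0.14), or 2.31-fold lower. Among genes higher in the GHSROS arrays, STK26, which encodes a kinase of the Ste20 family, averaged 7.26 ± 0.25 with the empty vector and 8.19 ± 0.22 with GHSROS, a log2 fold change of 0.93 (SE 0.16). In limma, however, 0 of the 18377 genes passed an adjusted p of 0.05, and every adjusted p was 1. At an unadjusted p under 0.05 there were 325 genes, 179 higher and 146 lower, where 919 would be reached by chance. Without GHSROS array 1 that count was 191, and with each array centred on its median it was 156 higher and 173 lower. Limma with an intensity trend and robust prior, or with array weights, also called 0. With the mean of the mitosis list or of the ATF4 list on each array as a covariate, both chosen after the data were seen, 3 genes passed, all lower, ZNF585B (adjusted p = 0.0106 and 0.00665) and LOC645188 (0.0032 and 0.00437) with either covariate. Groups without overlap were seen for 1012 genes, 5.5% of those tested, against 10% by chance.

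Of the 10 lower genes with the smallest p, none of which passed, the largest difference belonged to LOC645188, at 4.99 ± 0.30 (SD, n = 3) with the empty vector and 3.73 ± 0.25 with GHSROS (log2 fold change -1.26, SE 0.19). NLRP2, a pyrin domain protein of the NLR family that takes part in innate immune signalling, was lower by a log2 fold change of -0.79 (SE 0.10), with an unadjusted p of 0.000136 beside 5.9e-05 for ZNF585B. NDP encodes norrin, a secreted ligand of a Wnt receptor, and its log2 fold change was -0.62 (SE 0.10), as was that of PTPN22 (SE 0.10), a tyrosine phosphatase known from lymphocytes. MEST, an imprinted gene expressed from the paternal allele, differed by -0.70 (SE 0.15), and CRISPLD1, a secreted cysteine-rich protein gene, by -0.58 (SE 0.11). The zinc finger genes ZNF585A and ZNF611 differed by -0.44 (SE 0.09) and -0.47 (SE 0.10), and the small nucleolar RNA gene SNORA28 by -0.48 (SE 0.10). In each of these 10 genes the 3 GHSROS arrays all lay below the 3 empty-vector arrays, which choosing genes by the smallest p favours.

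The 10 higher genes with the smallest p likewise did not pass. In each the 3 GHSROS arrays lay above the 3 empty-vector arrays, which this choice of genes also favours. GNAL, a G protein alpha subunit that stimulates adenylyl cyclase, had the smallest p of these, 0.000621, and went from 7.10 ± 0.11 (SD) to 7.70 ± 0.11, a log2 fold change of 0.60 (SE 0.10). BICC1, which encodes an RNA-binding protein, was higher by 0.86 (SE 0.18) and SH3BGRL2 by 0.77 (SE 0.14). FZD3, a Wnt receptor of the frizzled family, was higher by 0.75 (SE 0.16). The autophagy kinase gene ULK2 differed by 0.58 (SE 0.11), MIPOL1 by 0.70 (SE 0.14) and TPD52L1 by 0.55 (SE 0.12). TPTE2, at a low level of 4.11 in the GHSROS arrays, differed by 0.52 (SE 0.11), and FBXO16, an F-box gene, by 0.45 (SE 0.09).

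**Figure D1:**
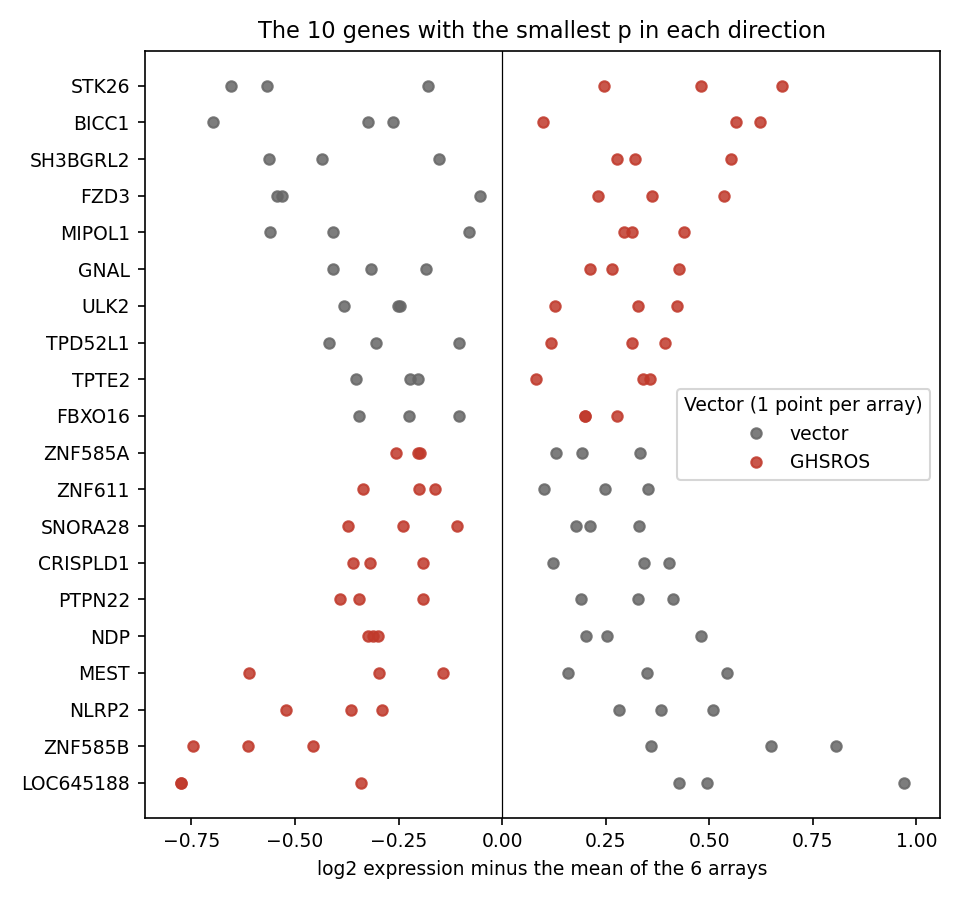
The horizontal axis gives log2 expression minus the mean of the 6 arrays, and each line of points is 1 gene, with grey points for the 3 empty-vector arrays and red points for the 3 GHSROS arrays. The 20 genes are the 10 with the smallest p in each direction, from STK26 (log2 fold change 0.93) to LOC645188 (-1.26), and none passed the adjusted p of 0.05. Both groups are separate in each of them, which choosing genes by the smallest p favours, so the separation is no further support.

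GHSROS itself was not read by a probe set that the annotation used here names for it, so the transfected transcript gave no check of the labels. GHSR, its host gene on the other strand, was at 5.82 ± 0.14 (SD, n = 3) with the empty vector and 5.82 ± 0.13 with GHSROS, and the 95% confidence interval of the log2 fold change ran from -0.27 to 0.26. That level lay below the array medians of 6.559 to 6.648, and whether GHSR is expressed in these cells cannot be told from these values. GHRL, the gene of the hormone ghrelin, was at 6.57 ± 0.12 and 6.58 ± 0.07, and its log2 fold change of 0.01 became -0.01 after either rescaling of the arrays. In the ghrelin axis list, 9 of 15 measured members were higher and 6 lower, 0 passed over all genes or adjusted over the list alone, and camera gave an adjusted p of 0.739. Its largest differences were 0.22 (SE 0.12) for MBOAT4, the acyltransferase that activates ghrelin, and 0.19 (SE 0.12) for SST, which encodes somatostatin. Both genes also lay below the array medians, MBOAT4 at 4.50 and SST at 5.72 with the empty vector.

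The arrays differed among themselves far more than between the groups. The difference between groups held 9.7% of the variance of all genes, and the first principal component held 64.4%. By construction the first component holds at least as large a share as any grouping of the arrays, so the gap alone says little about the labels. On that component, empty-vector array 1 and GHSROS array 3 lay together at -29.6 and -29, away from the other arrays at 4 to 22.2. Each of the 6 arrays correlated best with an array of the other group: empty-vector array 1 with GHSROS array 3 (r = 0.9972 across probe sets), empty-vector array 2 with GHSROS array 2 (0.997) and empty-vector array 3 with GHSROS array 1 (0.997). The margin was narrow for GHSROS array 2, which correlated with GHSROS array 1 at 0.9965. With each gene's mean over the arrays removed, it correlated slightly better with GHSROS array 1 (0.311) than with empty-vector array 2 (0.297). These correlations are across probe sets or genes, which are not independent replicates.

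**Figure D2:**
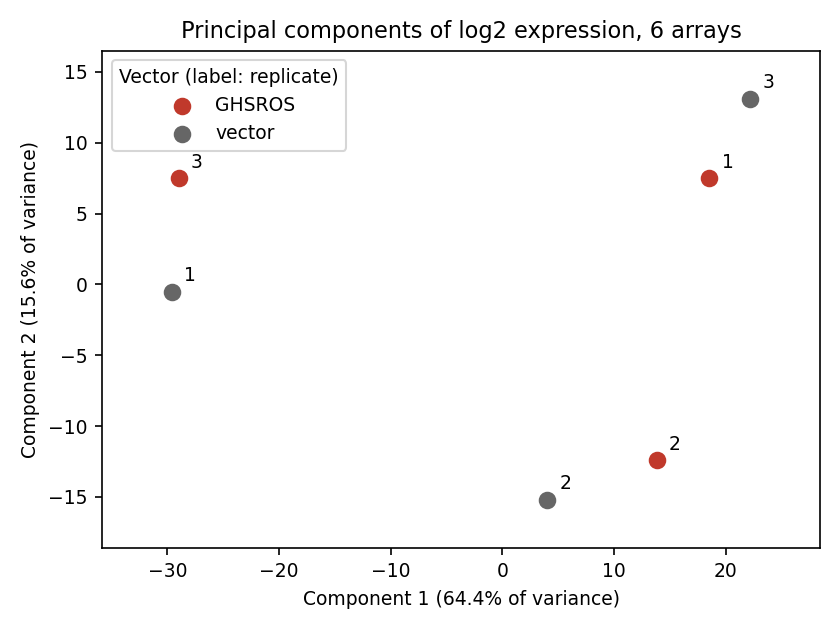
Each point is 1 array, placed by its scores on the first 2 principal components of log2 expression, which held 64.4% and 15.6% of the variance, with grey for the empty vector, red for GHSROS and the replicate number beside it. Empty-vector array 1 and GHSROS array 3 lie at -29.6 and -29 on the horizontal axis, apart from the other 4 arrays.

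Cell cycle genes followed those arrays and not the vectors. The mean of 40 mitosis and G2/M genes was 9.86 on empty-vector array 1 and 9.89 on GHSROS array 3, against 10.66 and 10.87 on the other empty-vector arrays and 10.85 and 10.80 on the other GHSROS arrays. Between the groups the list differed little, at 10.46 ± 0.53 (SD, n = 3) and 10.52 ± 0.54, with 31 of 40 members higher and 0 past the test over all genes or adjusted over the list alone (camera adjusted p = 0.733). Its largest differences were 0.26 (SE 0.28) for NUSAP1 and 0.13 (SE 0.44) for KIF23, both needed for the spindle or for cytokinesis. The DNA replication and G1/S genes, 17 of 38 higher and 0 past either test, gave an adjusted p of 0.884, with E2F2, a transcription factor of S phase entry, at 0.29 (SE 0.21) and the DNA ligase gene LIG1 at -0.21 (SE 0.18). Leaving out single arrays gave calls in both directions: without GHSROS array 3 mitosis genes were higher at an adjusted p of 4.97e-10, without empty-vector array 1 lower at 5.33e-06, and without empty-vector array 2 or 3 higher at 0.0302 and 0.0103. G1/S genes were lower without empty-vector array 1 (2.69e-08) and GHSROS array 1 (0.0378), and higher without GHSROS array 3 (0.00198) and empty-vector array 3 (0.00247). Omissions of 2 arrays were chosen after the data were seen. Mitosis genes were higher at 1.05e-13 without both arrays numbered 3, and at 0.00673 without both arrays that stood apart. All calls with arrays left out, here and for the lists below, use the preset correlation, and with an estimated correlation 0 lists were called under each of these omissions. For mitosis genes camera then gave an adjusted p of 0.88 without GHSROS array 3 and 0.761 without empty-vector array 1. It was 0.551 without both arrays numbered 3 and 0.837 without both arrays that stood apart.

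Genes of the unfolded protein response and of ATF4, the transcription factor of the amino acid stress response, ran the other way across arrays, at 10.31 on empty-vector array 1 and 10.32 on GHSROS array 3 and between 9.62 and 9.87 on the others. Between the groups 18 of 35 members were higher and 17 lower, with 0 past either test and an adjusted p of 0.983, and the list's median (0.02) and mean (-0.01) differed in sign. CHAC1, which degrades glutathione, differed by -0.28 (SE 0.82) and the serine synthesis gene PHGDH by -0.21 (SE 0.45). The list was lower without GHSROS array 3 (adjusted p = 0.0384) and higher without empty-vector array 1 (0.0164). Among p53 target genes, 15 of 26 were higher, 0 passed either test and camera gave 0.739. GDF15, a stress-induced cytokine gene, differed by 0.24 (SE 0.95) and SESN1 by 0.17 (SE 0.08).

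Genes of MHC class II antigen presentation, which display peptides to helper T cells, were lower in the GHSROS arrays in 11 of 13 measured members, with a mean log2 fold change of -0.31 and a median of -0.09. The list mean was 7.55 ± 0.305 (SD, n = 3) with the empty vector and 7.24 ± 0.28 with GHSROS. HLA-DPA1 and HLA-DPB1, the chains of the HLA-DP molecule, had log2 fold changes of -1.15 (SE 0.47) and -0.99 (SE 0.41), and the groups overlapped because GHSROS array 3 (9.54 for HLA-DPA1) lay above empty-vector arrays 2 and 3 (both 9.43). Camera with its preset correlation gave an adjusted p of 0.00057, and adjusted p = 0.993 with an estimated correlation. No member passed over all genes, and 0 passed adjusted over the list alone. An exact two-sided permutation test of the list mean gave p = 0.3, where 3 arrays against 3 cannot go below 0.1. The call was lost without empty-vector array 1 (adjusted p = 0.142), the array on which the list was highest at 7.90, and on which mitosis genes were lowest. The list was included because the study is remembered to have singled these genes out, possibly on these arrays, so its direction is not independent evidence. CD74, HLA-DRA and HLA-DRB1 were not analysed here, since no probe set was paired with 1 of these symbols alone.

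Genes of NF-kB cytokines and inflammation were higher in the GHSROS arrays in 26 of 36 members, with a mean log2 fold change of 0.14 and list means of 8.61 ± 0.23 (SD, n = 3) and 8.75 ± 0.19. PTGS2, the inducible cyclooxygenase, was higher by 0.84 (SE 0.24), and CSF3, the granulocyte colony-stimulating factor gene, by 0.54 (SE 0.14), both with the groups apart. The camera adjusted p was 0.00167, and adjusted p = 0.993 with an estimated correlation, and 0 members passed over all genes or adjusted over the list alone. The call was lost without GHSROS array 3 (adjusted p = 0.15), the array with the highest mean of 8.95, and without empty-vector array 3 (0.588), which had the lowest at 8.37. Empty-vector array 1 had the next highest mean at 8.82, so the list too was high on the arrays that stood apart. Without both arrays numbered 3 its direction turned (0.461).

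Interferon-stimulated genes were lower in 31 of 45 members, at list means of 7.62 ± 0.305 and 7.48 ± 0.295 (SD, n = 3) and a mean log2 fold change of -0.13. IFITM1, a membrane protein gene that restricts virus entry, differed by -0.74 (SE 0.45), and IFI27 by -0.64 (SE 0.22). The camera adjusted p was 0.0165, and adjusted p = 0.993 with an estimated correlation, with 0 members past either test. Across arrays the list followed the stress genes, at 7.95 on empty-vector array 1 and 7.82 on GHSROS array 3 and between 7.28 and 7.55 on the others. The call was lost without GHSROS array 1 (0.641) or 2 (0.254) and among the genes at or above the median level (0.685), and the direction turned without empty-vector array 1 (0.513). MHC class I genes were split 7 to 7, with 0 past either test and an adjusted p of 0.884, a median of 0.002 and a mean of -0.002 differing in sign. The largest differences were 0.17 (SE 0.12) for the peptide-trimming ERAP1 and 0.10 (SE 0.31) for the immunoproteasome gene PSMB10, and the list was lower without GHSROS array 3 (0.0222).

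**Figure D3:**
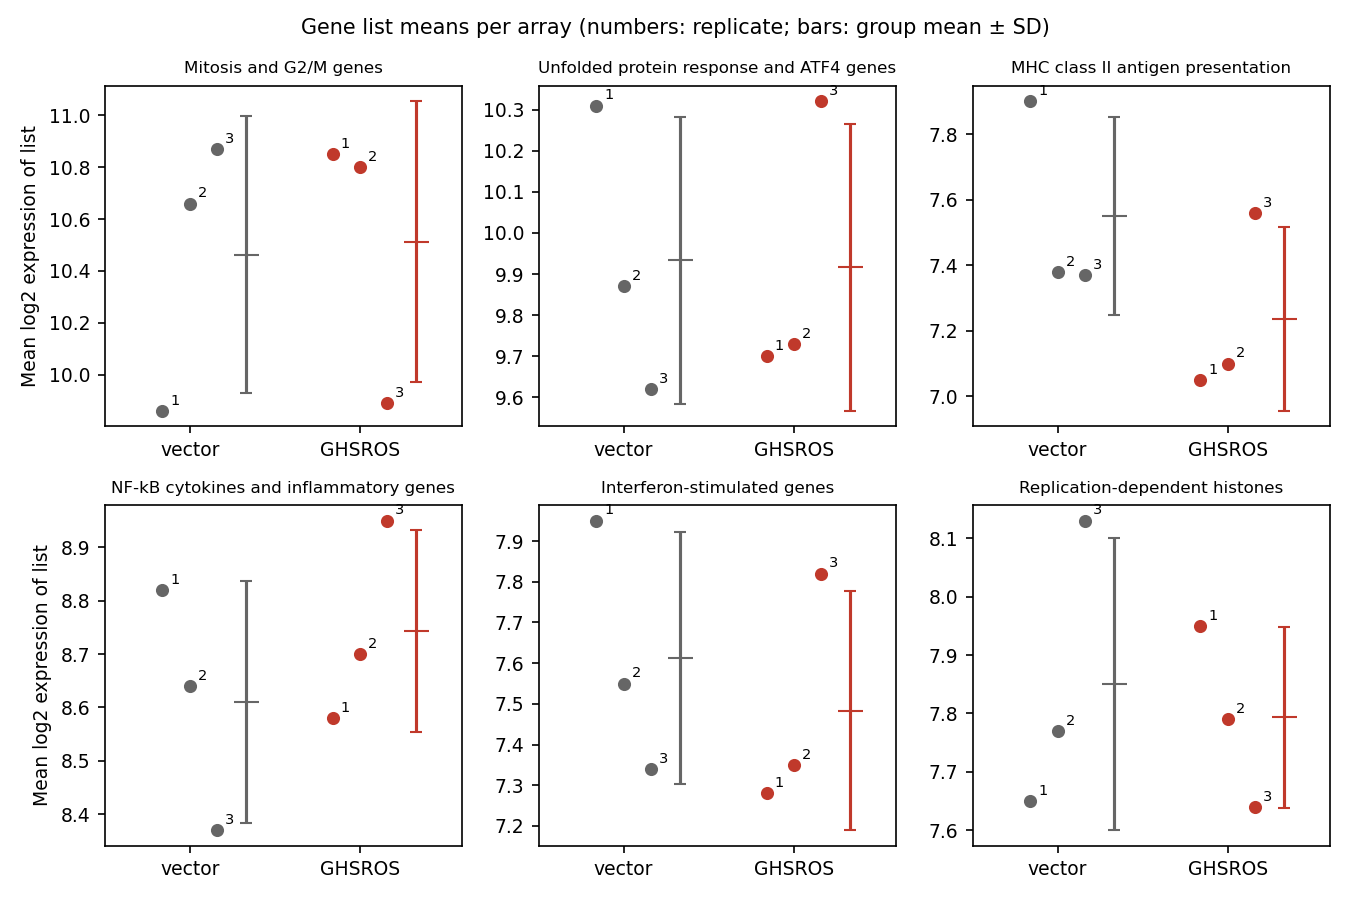
Each panel gives the mean log2 expression of 1 gene list on the vertical axis, with 1 point per array, its replicate number beside it, and a bar for the group mean ± SD, grey for the empty vector and red for GHSROS. Mitosis genes are lowest on empty-vector array 1 (9.86) and GHSROS array 3 (9.89), and the MHC class II list is highest on the same arrays (7.90 and 7.56), while both groups overlap in every panel.

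Ribosomal protein genes, oxidative phosphorylation genes and replication-dependent histone genes were slightly lower in the GHSROS arrays. The ribosomal list had 37 of 50 members lower at a mean log2 fold change of -0.04, with RPL28 at -0.19 (SE 0.11) and RPS24 at -0.13 (SE 0.33). In the oxidative phosphorylation list 35 of 52 were lower, at a mean of -0.04, with SDHD, a subunit of succinate dehydrogenase, at -0.26 (SE 0.10) and COX6B1, of cytochrome oxidase, at -0.16 (SE 0.09). Of the histone genes 33 of 44 were lower, at a mean of -0.06, with H2BC10 at -0.28 (SE 0.09) and H4C8 at -0.23 (SE 0.14). Camera gave each of these lists an adjusted p of 0.0373, and adjusted p = 0.993 with an estimated correlation, with 0 members past either test. On empty-vector array 1 and GHSROS array 3, where mitosis genes were lowest, oxidative phosphorylation genes stood at 10.34 and 10.32 and histone genes at 7.65 and 7.64, the lowest of the 6 arrays. Among the genes at or above the median level these calls were lost, at 0.122 for ribosomal proteins, 0.106 for oxidative phosphorylation and 0.0726 for histones. The ribosomal call was lost after quantile normalization (0.522) and without GHSROS array 1 (0.106) or 2 (0.201) or empty-vector array 1 (0.226) or 3 (0.4). The oxidative phosphorylation call was lost after quantile normalization (0.236) and turned without GHSROS array 3 (0.927) or empty-vector array 3 (0.91). The histone call was lost with the replicate number as a block (0.0563) and without GHSROS array 2 (0.0971), and turned without GHSROS array 3 (0.997) or empty-vector array 3 (0.281). Without both arrays numbered 3, both lists were called higher (oxidative phosphorylation 0.0337, histones 0.00202).

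Lists of cell movement, identity and metastasis genes differed between the groups by less than the SD between arrays. Mesenchymal and EMT genes were higher in 21 of 31 members (adjusted p = 0.521), with the EMT transcription factor gene SNAI1 at 0.30 (SE 0.11) and S100A4 at -0.23 (SE 0.20). Epithelial genes were higher in 14 of 31 (0.983), with the integrin gene ITGB4 at -0.52 (SE 0.39) and the adhesion gene EPCAM at 0.29 (SE 0.16), whose other probe set gave 0.82. Matrix protease and migration genes were higher in 20 of 35 (0.983) while camera's direction was lower, with the protease inhibitor gene TIMP3 at -0.30 (SE 0.34) and ITGB3 at 0.27 (SE 0.60). TGF-beta target genes were higher in 20 of 34 (0.739), with BHLHE40 at 0.31 (SE 0.45) and TGFB1 at -0.31 (SE 0.29). The lung metastasis genes known from this cell line were higher in 10 of 20 (0.378), with a median of -0.01 and a mean of 0.08, and with PTGS2 at 0.84 (SE 0.24) and IL13RA2 at 0.40 (SE 0.20). Bone metastasis genes were higher in 6 of 10 (0.739), with SPP1, the gene of osteopontin, at 0.62 (SE 0.40) and IL11 at 0.49 (SE 0.37). In all 6 lists 0 members passed over all genes or adjusted over the list alone. TGF-beta targets were higher without GHSROS array 1 (0.00541) and empty-vector array 1 (0.000573), lung metastasis genes without empty-vector array 1 (0.0438) and bone metastasis genes without GHSROS array 3 (0.0149). Without both arrays numbered 3, an omission chosen after the data were seen, TGF-beta targets were lower (0.000108). Epithelial genes were also lower there (0.011), and bone metastasis genes higher (0.000401).

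Metabolic and stimulus-responsive lists also had 0 members past either test. Genes of cholesterol and fatty acid synthesis were lower in 22 of 27 members (camera adjusted p = 0.236), with CYP51A1 at -0.19 (SE 0.25) and LSS at -0.18 (SE 0.27), both enzymes of sterol synthesis, and the list was lower without GHSROS array 2 (0.00219) or empty-vector array 3 (1.91e-07). NRF2 and glutathione genes were lower in 19 of 25 (0.378), with the transporter genes ABCC3 at -0.23 (SE 0.60) and ABCC2 at -0.18 (SE 0.21). Hypoxia and glycolysis genes were higher in 23 of 34 (0.59), with VEGFA, an angiogenic growth factor gene, at 0.31 (SE 0.41) and ANGPTL4 at -0.28 (SE 0.50). Immediate early and AP-1 genes were higher in 17 of 35 (0.739), with FOS at -0.32 (SE 0.28) and EREG, an EGF receptor ligand gene, at 0.27 (SE 0.18), a median of -0.001 and a mean of 0.01, and they were higher without empty-vector array 1 (0.0461).

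Markers of cells other than this line gave no list past the test and 0 members past either test. Leukocyte markers were lower in 13 of 19 members (adjusted p = 0.521), with CD14 at -0.34 (SE 0.67) and CD3D, a T cell receptor subunit, at 0.33 (SE 0.12) from a level of 4.77. CD14 stood at 8.98 on empty-vector array 1 and 8.09 on GHSROS array 3 and between 6.56 and 6.96 on the others. Fibroblast and endothelial markers were higher in 13 of 18 (0.625), with the receptor genes KDR at 0.41 (SE 0.53) and TIE1 at 0.17 (SE 0.43). Luminal breast markers were lower in 13 of 18 (0.739), with SPDEF at -0.41 (SE 0.61) and FOXA1, a luminal transcription factor gene, at 0.35 (SE 0.08) with the groups apart. Prostate markers were lower in 7 of 12 (0.739), with PMEPA1 at 0.18 (SE 0.36) and UGT2B17 at -0.17 (SE 0.10), a median of -0.02 and a mean of 0.003. Melanocyte markers were split 5 to 5 (0.885), with TYR, the tyrosinase gene, at 0.15 (SE 0.09) and PMEL at -0.09 (SE 0.21).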

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

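The covariates, the omissions of 2 arrays and the omissions with an estimated correlation were chosen after the data were seen, and the causes of the differences were not tested. The count of genes past the threshold, and of those changed 1.5-fold, stayed at 0 under every alternative fixed in advance, each single array left out included, and was 3, all lower, with the mitosis mean as a covariate (ZNF585B -1.19, adjusted p = 0.0106; LOC645188 -1.23, 0.0032; HLA-DPB1 -0.93, 0.0414) and 3, all lower, with the ATF4 mean (ZNF585B -1.20, 0.00665; LOC645188 -1.25, 0.00437; TNFSF10 -1.30, 0.0132). Of the 75 named genes, 24 changed sign in 61 of 1380 values, none with a call. Genes at an unadjusted p under 0.05 numbered 191 (without GHSROS array 1) to 480 (without empty-vector array 3) with single arrays left out, 187 and 76 of the fewer genes at or above the 25th percentile and the median level, 565 of all probe sets, 877 with array weights, 872 and 913 with the mitosis and ATF4 covariates and 1710 without both arrays numbered 3. Gene lists changed numbered 6, with 2 among genes at or above the median level, 14 without both arrays numbered 3, 0 with an estimated correlation, 0 with fry and 4 (without GHSROS array 2) to 9 (without empty-vector array 1) when leaving out single arrays. With an estimated correlation 0 lists were called under each omission of 1 or 2 arrays. Leaving out empty-vector array 1 and GHSROS array 3 gave 0 genes and 6 lists. Chromosome shifts went from 3 to 0 with an estimated correlation.

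Without both arrays numbered 3 these lists turned direction: NF-kB genes (adjusted p = 0.461), G1/S genes (1.31e-09), TGF-beta targets (0.000108), oxidative phosphorylation (0.0337) and histones (0.00202). In that setting 8 lists gained a call without turning. Mitosis (1.05e-13) and bone metastasis genes (0.000401) were higher. The ATF4 list (1.64e-05), cholesterol synthesis (4.94e-06), MHC class I (0.000727), epithelial (0.011), luminal (0.0272) and prostate genes (0.0233) were lower. Leaving out single arrays, some with a turned direction, gave adjusted p from 2.69e-08 to 0.687 for G1/S genes, 9.98e-06 to 0.927 for oxidative phosphorylation, 2.46e-06 to 0.997 for histones, 1.81e-08 to 0.641 for interferon-stimulated genes, 4.97e-10 to 0.201 for mitosis genes and 0.0164 to 0.878 for the ATF4 list. The MHC class II list ranged from 4.57e-06 to 0.142 over single arrays left out and kept its call under every other alternative except the estimated correlation and fry. Of 425 list values under alternatives, 287 kept direction and call, 34 lost a call, 24 gained one, 14 turned with a call on either side and 66 turned without one, which are not given singly.

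The replicate numbers did not pair the arrays: deviations from the group means correlated at -0.714, 0.504 and -0.669 for numbers 1, 2 and 3, and 2 of 6 arrays correlated best with their own number. Deviations correlated at 0.831 between empty-vector array 1 and GHSROS array 3, and at 0.738 between empty-vector array 3 and GHSROS array 1. No such crossed pairing was fitted, since it would be picked from the same values, and the unpaired tests do not take it into account. With the replicate number as a block, 0 genes passed, 223 reached an unadjusted p under 0.05 and 5 lists were called, the histone list (0.0563) no longer being among them. Signal over background is not given by these values, and dim genes were not filtered in the reported fit.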

Other observations

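The genes that differed most along the first principal component were chosen after their values were seen. NUPR1, a stress-induced chromatin protein gene, stood at 10.82 on empty-vector array 1 and 10.93 on GHSROS array 3, and between 6.61 and 6.79 on the other arrays. CST1, a cystatin gene, was at 13.20 and 13.01 on those arrays and between 8.61 and 10.81 on the others, and GDF15 at 11.83 and 12.20 against 8.89 to 9.82. The opposite course was seen for E2F8, a cell cycle transcription factor gene (7.69 and 7.74 against 8.96 to 9.51), the growth factor gene FGF1 (7.28 and 7.32 against 9 to 9.29) and TNC, the gene of the matrix protein tenascin C (9.08 and 8.92 against 10.42 to 10.94). TNFSF10, which encodes the death ligand TRAIL, was among these genes and had a log2 fold change of -1.35 between the vectors (SE 0.74, unadjusted p = 0.112), with an adjusted p of 0.0132 once the ATF4 mean was a covariate.

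Genes of chromosomes 10, 19 and 22 were lower in the GHSROS arrays in camera with the preset correlation, by medians of -0.06, -0.04 and -0.04 and adjusted p of 3.37e-05, 0.000782 and 0.0202, and adjusted p = 0.624, 0.766 and 0.766 with an estimated correlation.

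Tests chosen only after the result was seen were the splits for counts of genes, both tests of the resemblance between arrays, and the test of growth state for the MHC class II list. The estimated correlation was an alternative fixed in advance, with its bound for that list set after the result was seen. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. All 10 splits gave 0 genes past the threshold and all 10 gave 0 changed by 1.5-fold, the highest of the others also being 0. For genes at an unadjusted p under 0.05, 7 of 10 splits gave as many as the real 325, and the highest other gave 4187. That split exchanges the arrays numbered 3 and points to a structure of the samples that the groups as labelled do not follow. As many lists as the real 6 were called in 6 of the 10 splits, the highest other calling 20, and as many chromosomes as the real 3 in 2 splits, the highest other calling 3.

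The first pattern is that each array resembled an array of the other group most across probe sets, narrowly so for GHSROS array 2. A growth and stress state of the cultures is a candidate explanation. On a first component built without the lists, 100% of the mitosis members lay on the side opposite to empty-vector array 1 and GHSROS array 3, as that state needs. The list means had already shown mitosis genes low on those arrays, so this is no separate support. Of the ATF4 members 25.7% lay on that side too, where at most 25% was set after the data were seen, so this state stays open. An exchange of the labels of both arrays numbered 3 could account for 4 of the 6 arrays. It leaves empty-vector array 2 and GHSROS array 2, which correlated best with each other (r = 0.997), in opposite groups. From the side of GHSROS array 2 the margin was narrow, since it correlated at 0.9965 with GHSROS array 1. It was wider for empty-vector array 2, which correlated at 0.9949 with GHSROS array 1 and 0.9941 with empty-vector array 3. Exchanged labels would group empty-vector array 2 with the arrays it resembled least, empty-vector array 1 (0.9932) and GHSROS array 3 (0.9921). An exchange would leave the labelled split without genes that step cleanly between groups, and 4 such genes were found there (LOC645188, ZNF585B, NLRP2 and NDP). Of the 8 splits other than it and the exchanged one, that of empty-vector array 1 with GHSROS arrays 1 and 3 held 2 and the rest held 0. The exchanged split held 12. The labelled split thus exceeded all 8, the result set after the data were seen as speaking against an exchange. The larger count of 12 in the exchanged split goes the other way. An exact Poisson test of the labelled split against the highest of the 8, 2, gave p = 0.143. That test takes the highest count as a known rate, which is a strict choice. It treats genes as independent counts, and the bound on its p was set after the counts were seen. For those 4 arrays the exchange cannot be told apart from correct labels with so few genes, and a biological difference between cultures stays untested.

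The second pattern is the lower MHC class II list. With the correlation among its genes estimated from the arrays, camera gave p = 0.142, so genes that vary together may account for the call. The mitosis mean was nearly balanced, differing by only 0.051 between the groups. As a covariate it could therefore move the list little: reaching the bound of -0.156 needed a slope of -3.04, and the slope was -0.54. The difference of the list means was -0.284 (SE 0.041) with it and -0.312 (SE 0.24) without it. The list was still called at the preset correlation (camera adjusted p = 4.05e-07, and 6.77e-07 with the ATF4 mean). A linear effect of the mitosis mean thus carried little of the difference, but the test could not decide on a growth and stress state. Of the 10 splits 1, the real one, reached a camera p of 2.11e-05, the lowest of the others being 0.000112, but by the difference of the list means the real split (0.31) lay below 2 others (0.44 in both), and 10 splits are too few for a share under 0.05. The SE fell from 0.24 to 0.041 with the mitosis covariate, so little spread of the list mean was left that the mitosis mean did not follow. A difference of -0.284 beside that SE argues against such leftover variation as its whole cause, though the covariate was chosen after the data were seen. A growth and stress state and a response to GHSROS both stay open.

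The third pattern is ZNF585B with other step-like genes lower in the GHSROS arrays. Loss of a chromosome segment around ZNF585B in those cells could lower its neighbouring genes together, by a median of -0.3 or lower as set in advance. A median above -0.1 would have argued against it. The 10 measured genes on each side of ZNF585B, ZNF585A among them, had a median log2 fold change of -0.177, between these bounds, with 16 of 20 lower and a range of -0.47 to 0.21. Segment loss in part of the cells therefore cannot be told apart from regulation of these zinc finger genes or from signal shared between related zinc finger transcripts, which was not tested. The neighbours of the other step-like genes, LOC645188, NLRP2 and NDP, were not examined, so nothing is said on a cause for those.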
